A study of Homo sapiens with 18 samples.

How the data were processed

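Expression was measured on Agilent one-colour (Cy3) arrays, 1 file per array, with 62976 spots, of which 58717 were not controls. Per the file headers, the scanner images were read with Agilent Feature Extraction 10.7.1.1, which wrote for each spot an intensity after background subtraction and correction of spatial trends within the array, with no normalization between arrays. The authors also deposited a table of normalized log2 values for the same 18 arrays. Its normalization and any batch correction are not given in the sources used here. Its column medians lay between 7.07 and 7.10. Each of the 18 arrays correlated best with its own column of that table (r across probes, after centring each probe, 0.258 to 0.726). Batch accounted for 79.6% of the sum of squares within siRNAs in the scanner values and for 11.7% in the deposited table, and its scale and centring between genes were not resolved further. The table served as an alternative.

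The labels assign the arrays to 5 siRNAs, 3 batches and 14 RNA samples, and mark 4 arrays as technical. The design text gives more repeats for siRNAs #2 and #3 than the labels mark as biological; the labels were used. Each batch was 1 slide. Batch 1 held NT1, siRNA #2 and siRNA #3, and batches 2 and 3 held NT2 and all TYRP1 siRNAs. NT1 and NT2 are therefore linked only through the arrays of siRNAs #2 and #3, which lay in batch 1 and in the other batches. The same holds for NT1 and siRNA #1. No depth applies to arrays; between 61.5% and 79.3% of probes per array were well above background, and the number of arrays limits the precision.

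The values analysed were log2 of the processed intensity minus each array's 75th percentile. Control spots and outlier spots were left out, and spots of 1 probe were averaged, which left 42405 probes; 530 probes that were outliers on every spot of an array were not tested. Accessions of 25422 probes matched a gene symbol in the NCBI RefSeq table supplied (19483 symbols), and the other 16983 probes stayed unnamed. A probe was tested if it was well above background on at least 0.5 of the arrays of 1 siRNA, and the probe with the highest mean signal stood for its gene. This gave 27355 features, of which 15819 had a symbol. Tested probes of 1 gene could differ in pooled log2 fold change. The range was 0.86 to 1.71 for COL19A1, -0.09 to 0.82 for WIPF3 and -1.33 to -0.26 for CHRDL2. It was 0.08 to 0.31 for MOV10, 0.10 to 0.40 for CCNG1 and -0.24 to -0.06 for TNRC6C. Probes of some other genes were close, such as TPD52L1 (-2.05 to -1.82) and CTSA (-0.33 to -0.32). A gene with no probe well above background on any array of a siRNA has only a bound there. Its change is given as "at least N-fold", the mean log2 value of the brighter arm against the mean of the dimmer arm with dim values raised to the lowest value well above background on that array. These bounds are means over RNA samples without batch adjustment, and the adjusted p beside them comes from the fit.

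Differences were tested with limma 3.58.1 (lmFit and eBayes; statmod 1.5.0, R 4.3.3), with 5 siRNA groups and batch as fixed terms and the RNA sample as a random block (duplicateCorrelation, consensus correlation 0.558 from a seeded subset of features). The residual degrees of freedom were 11, plus 2.40 from the prior. Pooled changes are the mean of the 3 TYRP1 siRNAs minus the mean of NT1 and NT2. P-values were adjusted by Benjamini-Hochberg per comparison, with a threshold of 0.05. Differences among the TYRP1 siRNAs were tested with a moderated F test and pairwise contrasts. Batch-adjusted values per RNA sample were used for the permutation tests of TYRP1 and RAB17, over all 3003 splits. The batch adjustment was fitted with the real siRNA groups and not refitted for each split. The siRNAs were also unevenly spread over the batches, and the splits took samples of 1 siRNA as exchangeable with those of another. These p-values are therefore approximate and do not measure the spread between siRNAs. The 24 gene lists were tested with camera (preset correlation 0.01, and estimated), which compares a list with the other features, and with fry, on values whitened for the RNA-sample correlation. Fry, which asks whether a list's genes move one way on balance, passed 7 lists in the pooled comparison, and its mixed test, for change in either direction, passed 20.

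Before the data were examined, the groups, tests, gene lists, alternatives and the rule for named genes were fixed. The rule names TYRP1 and RAB17; the 10 highest and 10 lowest pooled changes past the threshold with the same sign for each siRNA; the 5 highest and 5 lowest for each siRNA; the 4 highest and 4 lowest for NT2 against NT1 and for the pair of siRNAs with the smallest F-test p; and up to 4 members past the threshold per list, or the 2 with the smallest p. Other genes are said to be named after their values were seen. The alternatives covered normalization, centring, the deposited table, the probe filter, the probe per gene, batch, the technical arrays, array weights, the variance prior, the controls, the threshold and single RNA samples. The background correction with normexp (offset 50) used the median spot signal, because the files hold no mean signal. A batch 3 exclusion and counts against each control separately were added after seeing the data. So were tests on RNA samples that did not choose the calls: the calls came from a fit without some samples of NT1 and of siRNAs #2 and #3, or without 1 sample of siRNA #3 (and then also without 1 of siRNA #1 or #2), and the change was measured on the samples left out.

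The fit was tested on simulated data with the fitted spread of each gene, the real batches and the duplicate correlation for 27355 features. The simulated spread was the same in all siRNA groups and the genes were independent. Real NT1 samples were further apart than the others, so the rates below do not cover that case. In the pooled comparison it recovered 80.6% of 67 genes changed by 1.0 log2 unit and 34.3% of 67 changed by 0.5, and 3.29% of its calls were false. For siRNA #1 it recovered 73.1% and 11.9%, for siRNA #2 67.2% and 11.9%, and for siRNA #3 76.1% and 22.4%. In NT2 against NT1, simulated without a difference, it called 0 features. Correlations between siRNAs were set against 20 simulations of unchanged groups with the same controls, without a difference between NT1 and NT2.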

Results

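Gene expression was measured in 501Mel, a pigmented human melanoma cell line, 3 days after transfection with 50 nM of 1 of 5 siRNAs. NT1 and NT2 were non-targeting controls. siRNAs #1, #2 and #3 were directed at TYRP1, which codes for a melanosomal enzyme of eumelanin synthesis. The 18 one-colour arrays carried 14 RNA samples: 3 each for NT1, NT2, siRNA #1 and siRNA #3, and 2 for siRNA #2. Of the arrays, 4 were technical repeats of RNA from siRNAs #2 and #3 in another batch. All n below count RNA samples. Between 61.5% and 79.3% of the probes on an array were well above background, and the 75th percentile of the signal lay between 489 and 776. The number of arrays limits the precision. The labels call these RNA samples biological replicates without saying whether they came from separate cultures, so the p-values measure only the spread between them.

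The first question was how far each siRNA lowered its target. TYRP1 (NCBI gene 7306) was lower in all 8 RNA samples with a TYRP1 siRNA than in any of the 6 control samples. Its batch-adjusted log2 signal, relative to the array's 75th percentile, was 7.80 ± 0.074 (SD, n = 3) with NT1 and 7.62 ± 0.094 (SD, n = 3) with NT2. It was 5.96 ± 0.10 (SD, n = 3) with siRNA #1, 5.36 ± 0.0090 (SD, n = 2) with siRNA #2 and 4.47 ± 0.10 (SD, n = 3) with siRNA #3. TYRP1 mRNA was thus at 29.7% of the controls with siRNA #1 (95% confidence interval 26.2% to 33.6%), 19.7% with siRNA #2 (17.3% to 22.3%) and 10.5% with siRNA #3 (9.41% to 11.8%). The pooled log2 fold change was -2.45 (SE 0.060, limma adjusted p = 5.04e-11). The two-sided permutation test of 8 against 6 samples gave p = 0.000333, the smallest it can give. This p is approximate, since the values were batch-adjusted with the real siRNA groups. It also takes the RNA samples as exchangeable although they are grouped by siRNA, so it does not measure the spread between siRNAs. The siRNAs differed from each other in this effect (F-test adjusted p = 8.36e-06), whereas NT2 and NT1 differed by -0.18 (adjusted p = 0.269). Within batch 1, batch 2 and batch 3 the log2 fold changes were -2.88, -2.39 and -2.29. The batch 2 value, with 2 residual degrees of freedom, did not pass (adjusted p = 0.0661), and batch 3 had 1 array per siRNA and no test. The second TYRP1 probe gave a pooled value of -2.77.

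RAB17 (NCBI gene 64284), a small GTPase of endosomal and melanosome trafficking, fell as well. Its pooled log2 fold change was -0.54 (SE 0.079, adjusted p = 0.00127), or 68.6% of the control level (95% confidence interval 61.0% to 77.2%). All 8 knock-down samples lay below all 6 control samples (two-sided permutation p = 0.000333, again the smallest possible). This p is approximate for the same reasons and does not measure the spread between siRNAs. The values were -0.56 with siRNA #2 (adjusted p = 0.0192) and -0.67 with siRNA #3 (adjusted p = 0.000758), both past the threshold, and -0.40 with siRNA #1 (adjusted p = 0.0647), which was not. A difference among the siRNAs was not detected (F-test adjusted p = 0.459). Within batches 1, 2 and 3 the values were -0.55, -0.67 and -0.59, of which the batch 2 value did not pass (adjusted p = 0.178). The second RAB17 probe gave -0.77.

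**Figure D1:**
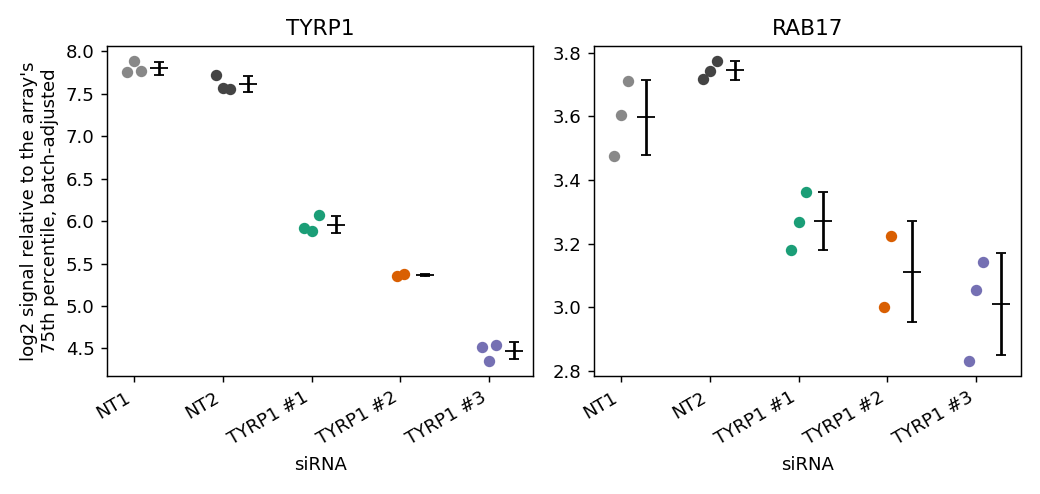
Batch-adjusted log2 signal of TYRP1 (left) and RAB17 (right) relative to the array's 75th percentile, by siRNA; each point is 1 RNA sample, and the bars give the mean and SD of 2 or 3 samples. All 8 knock-down samples sit below all 6 control samples for both genes, and the 2 vertical axes differ in range.

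The pooled comparison asked which genes changed with the TYRP1 siRNAs as a whole. Among genes that rose were COL19A1, a fibril-associated collagen (log2 fold change 1.71, SE 0.14, adjusted p = 2.31e-05), CHGA, a secretory granule protein (1.58, SE 0.14, adjusted p = 3.83e-05), IFI44, an interferon-induced gene (1.43, SE 0.20), BFSP1, a lens intermediate filament protein (1.37, SE 0.11), WWC3 (1.36, SE 0.099), and CLDN20, a claudin (1.23, SE 0.16). The antisense RNA LPP-AS2 was 2.54-fold higher (adjusted p = 0.0149). UBASH3B, DORIP1 and KRCC1 were not well above background on any NT1 array and were at least 1.43-fold, 1.47-fold and 1.58-fold higher (adjusted p = 0.00507, 0.00743 and 0.0314). Against NT2 alone UBASH3B, DORIP1, KRCC1, IFI44 and LPP-AS2 did not pass (adjusted p = 0.403, 0.539, 0.93, 0.166 and 0.242), nor did WWC3 (adjusted p = 0.0545) or CLDN20 (adjusted p = 0.0602). Among genes that fell, OC90, an otoconial protein, had the lowest value (-2.80, SE 0.15, adjusted p = 6.02e-07), ahead of TYRP1. STRA6, a retinol transporter (-2.07, SE 0.26), TPD52L1 (-2.05, SE 0.18) and MYH7B, a myosin heavy chain (-1.90, SE 0.24), followed. CHI3L1, a secreted chitinase-like protein, and TIE1, an endothelial receptor kinase, were not well above background with any siRNA except NT1, and were each at least 1.90-fold lower (adjusted p = 1.63e-05 and 0.0031). STRA6 and TIE1 did not pass against NT2 alone (adjusted p = 0.22 and 0.29). ADGRF5 was at least 1.67-fold lower (adjusted p = 0.00304), but did not pass against NT2 alone (adjusted p = 0.248). TRIM17 and LAMB4 were at least 2.07-fold and 1.32-fold lower (adjusted p = 0.0480 and 0.0473). Neither passed against NT1 alone (adjusted p = 0.133 for TRIM17 and 0.334 for LAMB4), against NT2 alone (adjusted p = 0.174 and 0.0795) or without batch 3 (adjusted p = 0.137 and 0.235), and LAMB4 was not well above background on any NT1 array. In all, 2554 of 27355 features passed an adjusted p of 0.05, 1201 higher and 1353 lower, and 125 of them changed at least 2-fold. The median of all features was -0.07, and the balance depended on centring: 47.0% of the calls were higher here, 81.7% with arrays centred on their median, where the median of all features was 0.03, and 58.1% after quantile normalization.

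Much of this list rested on 1 of the controls. Against NT1 alone 6295 features passed, against NT2 alone 449, and 140 passed against both with the same sign (68 higher, 72 lower), a count taken after the data were seen. Independent lists of these sizes would share 52.7 with the same sign. The 2 comparisons are not independent, since both use the same TYRP1 siRNA samples, which raises the overlap further. Of the 103 genes named by rule for any comparison, 92 passed in the pooled comparison. Of these, 12 passed against each control, 68 against NT1 only, 7 against NT2 only and 5 against neither, and 10 had the other sign against NT2 (CD52, CHRDL2, DCN, FN1, GULP1, KRCC1, MOV10, PLK2, WIPF3 and WIPI1). Fewer features passed against NT2, which makes the adjusted threshold stricter there. Passing against NT1 only thus does not by itself show a smaller change against NT2. The 12 were ABCB5, BCL2A1, BFSP1, CHGA, COL19A1, IFIT1, ISG15, KRT5, MYH7B, RAB17, RHD and TYRP1. Of these, KRT5 was not well above background on any array of NT1 or siRNA #3, nor RHD with any siRNA except #3. Against NT2, OC90 and TPD52L1 did not pass (adjusted p = 0.774 and 0.596) and CHI3L1 was not well above background in either arm. OC90 was -0.18 within batch 2, where NT2 was the control, and -5.38 within batch 1, where NT1 was. The genes that passed against each control, named here after their values were seen, included CHGA (1.85 against NT1, 1.31 against NT2), COL19A1 (1.19 against NT2 and higher against NT1), BFSP1 (2.02 and 0.71), ISG15, a ubiquitin-like interferon-induced protein (1.07 and 0.78), MLH3, a DNA mismatch repair gene (0.92 and 0.94), and ABCB5, a transporter of the ABC family (0.75 and 0.85). The pooled change of ABCB5 ranged from -0.07 to 0.80 over its 3 tested probes. Those that fell against both included TYRP1 (-2.54 and -2.36), MYH7B (-2.35 and -1.46), PLB1, a phospholipase (-1.91 and -1.03), A2M, a protease inhibitor (-1.52 and -1.05), and VSTM1 (-1.67 and -1.23). Within batch 1 2744 features passed, and within batch 2 none passed in limma (3251 at an unadjusted p under 0.05). Batch 2 left 2 residual degrees of freedom, and TYRP1 did not pass there either. Between batches 1 and 2, which share no control siRNA, the log2 fold changes correlated across genes at r = 0.123, and genes are not independent replicates. The 2 batches share RNA of sample 6 of siRNA #3 and sample 7 of siRNA #2, and siRNA #1 was in batch 2 only of these 2. Of the pooled calls, which were chosen on these same arrays, 98.9% had the same sign within batch 1 and 87.7% within batch 2. Leaving out 1 RNA sample moved the pooled count by over 1.5 times for sample 26 of siRNA #3 (1182), samples 7 and 27 of siRNA #2 (1274 and 1311), samples 2 and 32 of NT2 (1380 and 1585) and sample 34 of siRNA #1 (1679). Without batch 3, left out after its lower share of probes above background was seen, it was 837.

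**Figure D2:**
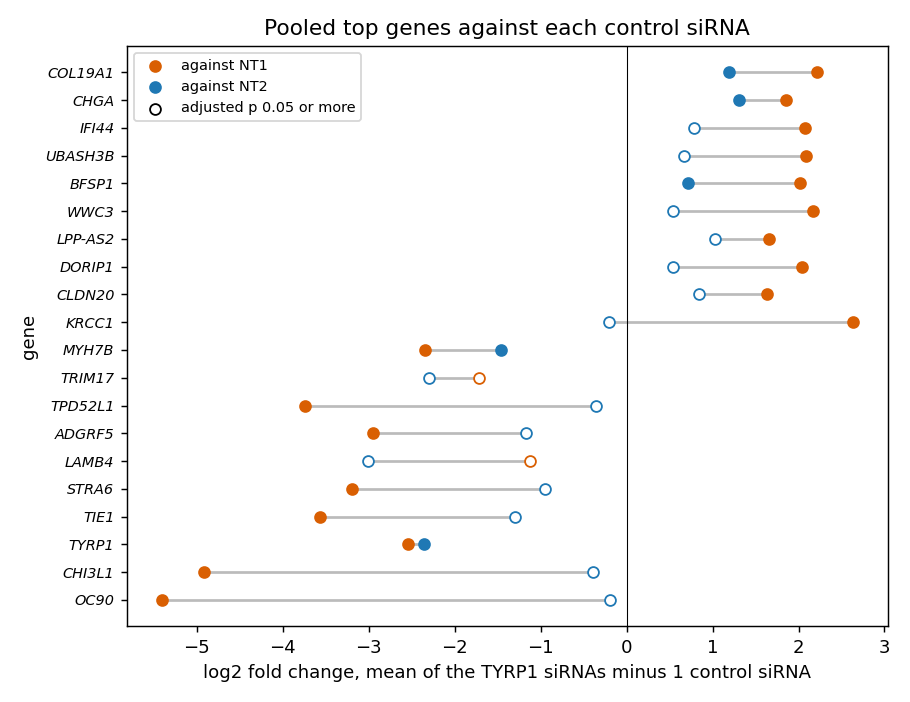
Log2 fold change of the mean of the TYRP1 siRNAs against NT1 (orange) and against NT2 (blue) for the 10 highest and 10 lowest genes of the pooled comparison, from the fit with batch as a term; filled points passed an adjusted p of 0.05, and values of dim genes are fitted values, not bounds. TYRP1 lies at -2.54 and -2.36, while OC90 and CHI3L1 lie far below 0 against NT1 alone.

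Among the 24 gene lists fixed before the data were examined, 4 passed camera in the pooled comparison. Of 28 measured interferon-response genes 13 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.35. ISG15 (0.92, SE 0.094), IFI44 (1.43, SE 0.20), IFIT1 (0.65, SE 0.089) and IFIT5 (0.53, SE 0.076) rose, and OAS2 fell (-0.34). Of these, IFI44 and IFIT5 did not pass against NT2 alone (adjusted p = 0.166 and 0.0621). Of 17 histone genes 10 rose and 0 fell (14 and 0 adjusted over the list alone; median 0.28), among them H4C1 (0.45), H3C1 (0.44), H1-2 (0.37) and the variant H2AZ1 (0.32). None of these 4 histone genes passed against NT2 alone (adjusted p = 0.295, 0.695, 0.476 and 0.323), and the histone list was also higher with NT2 than with NT1 (median 0.27, 16 of 17 positive). The immune-cell markers were lower (median -0.21), with 1 of 13, the macrophage lysosomal protein CD68, past the threshold (-0.62; 3 adjusted over the list alone), though not against NT2 alone (adjusted p = 0.108). So were 7 endothelial markers (median -0.46), of which TIE1 and KDR fell (5 adjusted over the list alone), though neither passed against NT2 alone (adjusted p = 0.29 and 0.767). KDR was not well above background on any NT1 array and has no fold here. TIE1 was not well above background with any siRNA except NT1, so the endothelial median and test include fitted values of dim genes. These 4 lists passed camera with a preset correlation of 0.01, at adjusted p = 4.29e-11, 4.29e-11, 0.0341 and 0.00835. None passed with an estimated correlation (adjusted p = 0.172, 0.172, 0.533 and 0.172). The count of lists was 7 with median centring and 8 without the filter on dim probes. Counted after the data were seen, 3 lists passed camera against NT1 and against NT2: the interferon and histone lists, higher against both, and the oxidative phosphorylation list, higher against NT1 (median 0.15) and lower against NT2 (median -0.14). None passed with an estimated correlation (lowest adjusted p = 0.542 against NT1 and 0.412 against NT2). The interferon median was 0.50 against NT1 and 0.25 against NT2, and 0.63, 0.18 and 0.36 within batches 1, 2 and 3. The histone median was 0.35 against NT1 and 0.18 against NT2, and 0.31, 0.07 and 0.35 within the batches. Within batches 1, 2 and 3 the immune-marker median was -0.33, -0.12 and -0.06, and the endothelial median -0.37, -0.05 and -0.34. Fry, which does not compare a list with other genes, passed these 4 lists and 3 others, the melanocyte, lysosome and p53 lists.

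With single siRNAs, camera at the preset correlation passed 5 lists with siRNA #1, 4 with siRNA #2 and 9 with siRNA #3. None passed with an estimated correlation (lowest adjusted p = 0.264, 0.214 and 0.153). Other splits of the samples in the pooled comparison, described below, passed a median of 6 lists and at most 10 at the preset correlation. Relative to the other features, siRNA #1 gave higher histone (adjusted p = 5.08e-14), ribosomal protein (median 0.135, adjusted p = 1.11e-05), G1/S and mitosis lists and lower immune markers (adjusted p = 0.0137 for these 3). Of single genes, 8 of 17 histone genes rose, and 0 of 30 ribosomal protein and 0 of 37 G1/S genes passed. Of 35 mitotic genes 1 rose and 1 fell, and 1 of 13 immune markers fell. With siRNA #2 the interferon (adjusted p = 2.22e-11), histone (adjusted p = 1.13e-05) and unfolded-protein-response lists (median 0.234, adjusted p = 0.00178) were higher and endothelial markers lower (adjusted p = 0.00409). There 10 of 28 interferon genes rose and 1 of 7 endothelial markers fell. None of 17 histone or 25 unfolded-protein-response genes passed. With siRNA #3 the interferon (15 rose and 1 fell, adjusted p = 2.28e-14), histone (3 rose and 0 fell, adjusted p = 5.38e-05), hypoxia (4 rose and 3 fell, adjusted p = 0.0185) and RAB lists (6 rose and 3 fell, adjusted p = 0.0232) were higher. Lower with it were the lysosome (10 of 28 fell, adjusted p = 0.0022), ribosomal protein (3 of 30 fell, adjusted p = 0.0185), cholesterol-synthesis (4 of 25 fell, adjusted p = 0.0288), immune (adjusted p = 0.0288) and endothelial lists (adjusted p = 0.0232).

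In the pooled comparison the pigment-cell and microRNA lists moved both ways and did not pass camera. Of 27 melanocyte genes 2 rose and 4 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.387). By fry the melanocyte list, which holds TYRP1 itself, was lower on balance, with the smallest fry p of the 24 lists (adjusted p = 7.58e-05). Fry tests against 0 and not against other features, and TYRP1 was not left out of the list. The melanocyte median was -0.07, as was the median of all features. TYRP1, its neighbour in the melanin pathway DCT (-0.45, SE 0.064) and the transporter SLC45A2 (-0.40, SE 0.095) fell, and the survival gene BCL2A1 rose (0.35, SE 0.067). DCT was -0.82 against NT1 and -0.09 against NT2. Of 37 listed targets of miR-16, a microRNA that has been studied as bound by TYRP1 mRNA, 4 rose and 2 fell (4 and 4 adjusted over the list alone; adjusted p = 0.780). HMGA2, a chromatin protein (0.88, SE 0.095), rose, while RAB17 and the cytokinesis gene ANLN (-0.41, SE 0.077) fell. HMGA2 was 1.62 against NT1 and 0.15 against NT2, and its tested probes gave pooled changes of 0.24 to 0.88. SLC45A2 and ANLN did not pass against NT2 alone (adjusted p = 0.604 and 0.0967). For both lists the sign of the median and of camera's test is read against the other features; the miR-16 median was -0.07, with camera pointing up.

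In the same comparison, of 28 lysosome and autophagy genes 1 rose and 5 fell (1 and 7 adjusted over the list alone), with the proteases CTSD (-0.69, SE 0.11) and CTSA (-0.32, SE 0.053) and the cholesterol carrier NPC1 (-0.48, SE 0.073) lower and WIPI1 (0.39, SE 0.081) higher. Of 30 RAB and trafficking genes 4 rose and 3 fell (6 and 4 adjusted over the list alone), with RAB35 (0.42) and RAB8B (0.47) higher and RAB5B (-0.66) lower. Of 20 MAPK feedback genes 1 rose and 3 fell (1 and 5 adjusted over the list alone): EPHA2 (-1.01, SE 0.11), MAFF (-0.61) and DUSP4 (-0.37) fell and SPRED1 (0.37) rose. Of 26 genes of invasive or dedifferentiated melanoma 3 rose and 4 fell (5 and 5 adjusted over the list alone), among them ABCB5 (0.80) and ZEB2 (0.33) higher and the matrix genes FN1 (-0.72) and CCN1 (-0.39) lower. The 3 tested probes of ABCB5 gave -0.07 to 0.80, so its rise was not shared by all of them. FN1 was -1.71 against NT1 and 0.26 against NT2. Of 25 neural crest, matrix and adhesion genes 3 rose and 2 fell (5 and 3 adjusted over the list alone), with TIMP1 (0.58) and MMP2 (0.53) higher and LAMC1 (-0.45) and MCAM (-0.34) lower. Of 26 hypoxia and glycolysis genes 3 rose and 3 fell (4 and 3 adjusted over the list alone), with P4HA1 (0.38) and GPI (0.33) higher and ADM (-0.83) and NDRG1 (-0.40) lower. Of 19 RNA-interference genes 1 rose and 3 fell (3 and 3 adjusted over the list alone), with MOV10 (0.31) higher and ADARB1 (-0.60), DGCR8 (-0.37) and TNRC6C (-0.24) lower. Of the genes named in this paragraph, ABCB5 passed against each control, LAMC1 (-0.01 against NT1, -0.89 against NT2) and NDRG1 (-0.09 and -0.71) against NT2 only, MCAM against neither and the others against NT1 only. Among those others ADARB1 (-0.59 and -0.61) and ZEB2 (0.30 and 0.37) changed at least as much against NT2, and the rest less. WIPI1 was 1.01 against NT1 and -0.22 against NT2, MOV10 0.69 and -0.08, TIMP1 1.15 and 0.01, NPC1 -0.88 and -0.08, and CTSD -1.05 and -0.33. Against NT2 the adjusted p was 0.651 for MMP2, 0.805 for DGCR8 and 0.913 for TNRC6C. In the pooled comparison none of these 7 lists passed camera (lowest adjusted p = 0.188), and by fry the lysosome list was lower on balance (adjusted p = 0.00101).

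Cell-cycle, stress and housekeeping lists showed few calls in the pooled comparison and none passed camera there. Of 37 G1/S and replication genes 1 rose, the cyclin CCNE2 (0.33; 1 adjusted over the list alone). Of 35 mitotic genes CCNB2 rose (0.23) and ANLN and AURKB (-0.27) fell (1 and 2 adjusted over the list alone). Of 26 p53 targets CCNG1 rose (0.40) and PLK2 fell (-0.27, with 1 and 2 adjusted over the list alone), and the list was lower on balance by fry (adjusted p = 0.0124). Fry tests against 0, and the p53 median (-0.03) lay above the median of all features (-0.07). A difference of the p53 list from the other features was not detected by camera (adjusted p = 0.780). Among 25 unfolded-protein-response genes SEL1L rose (0.32) and CALR fell (-0.24), with 0 adjusted over the list alone. Among 25 cholesterol-synthesis genes SC5D fell (-0.53; 1 adjusted over the list alone). Among 25 BCL2-family genes BCL2A1 rose and BIK fell (-0.79; 1 and 1 adjusted over the list alone). None of 30 ribosomal protein genes or 27 oxidative phosphorylation genes passed in limma, over all genes or adjusted over the list alone; the smallest p belonged to RPS23 (0.17, adjusted p = 0.192) and RPS3, and to NDUFV1 (-0.18, adjusted p = 0.0594) and NDUFS3. Among 15 housekeeping genes HPRT1 rose (0.49) and TFRC fell (-0.57; 1 and 1 adjusted over the list alone). Of 7 keratinocyte markers 2 rose, KRT10 (0.34) and ITGB4 (0.39), and 1 fell, KRT5, which was too dim for a fold (2 and 1 adjusted over the list alone). Of 7 fibroblast markers DCN fell (-0.52; 1 rose and 1 fell adjusted over the list alone). DCN was -1.47 against NT1 and 0.44 against NT2, and PLK2 was -0.66 and 0.12. Of the genes named in this paragraph that passed, BCL2A1 and KRT5 passed against each control, CCNE2, CCNG1, SC5D and ITGB4 against NT2 only, CALR against neither and the others against NT1 only.

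**Figure D3:**
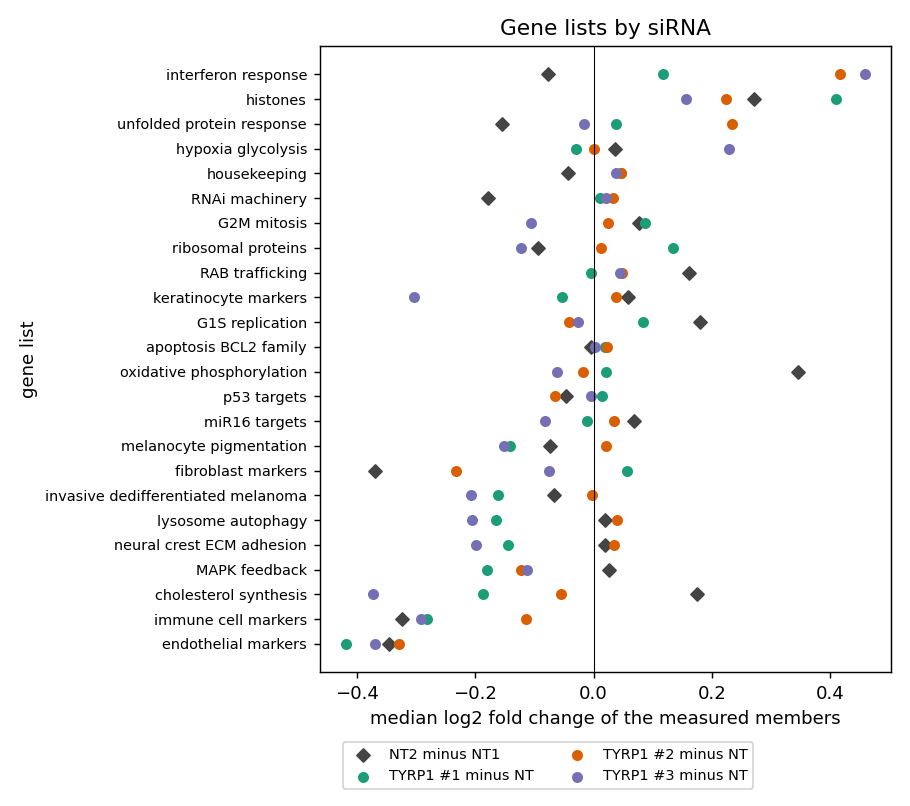
Median log2 fold change of the measured members of each of the 24 gene lists, for each TYRP1 siRNA against the mean of the controls (circles) and for NT2 against NT1 (diamonds). The interferon-response medians are 0.12, 0.42 and 0.46 with siRNAs #1, #2 and #3 and -0.08 for NT2 against NT1.

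The control siRNAs were then set against each other. OC90 (-5.21, SE 0.26, adjusted p = 6.71e-07), CHRDL2, a secreted BMP-binding protein (-3.84, SE 0.34), and the lymphocyte surface antigen CD52 (-3.66, SE 0.31) were lower with NT2 than with NT1, and CHI3L1 was at least 6.95-fold lower. WIPF3 was higher with NT2 (2.94, SE 0.28, adjusted p = 7.68e-05). COL13A1, a transmembrane collagen, KRCC1 and GULP1, an engulfment adaptor, were not well above background on any NT1 array and were at least 5.24-fold, 3.48-fold and 1.74-fold higher. In all 2904 features passed, 1300 higher and 1604 lower, with 671 changed at least 2-fold and a median of all features of -0.11. Of the pooled knock-down calls, 34.9% were also called here, against 10.6% of all features. Higher with NT2 by camera were 6 gene lists: oxidative phosphorylation (median 0.34, adjusted p = 6.68e-07), histones (adjusted p = 0.000596), RAB and trafficking (median 0.16, adjusted p = 0.0142), G1/S and replication (median 0.18, adjusted p = 0.0211), mitosis (median 0.08, adjusted p = 0.0320) and cholesterol synthesis (median 0.17, adjusted p = 0.0352). None passed with an estimated correlation (lowest adjusted p = 0.705) or by fry (lowest adjusted p = 0.0575). NT1 and NT2 shared no batch, so this difference was reached only through the arrays of siRNAs #2 and #3. It fell to 212 features without the 4 technical arrays and was 6160 without a batch term, and leaving out samples 32 and 22 of NT2 or sample 21 of NT1, 1 at a time, gave 1176, 1764 and 1552.

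Each siRNA was also compared with the controls by itself. With siRNA #1, WIPF3 (2.03, SE 0.22), DPP4, a surface peptidase (1.73, SE 0.23), and BFSP1 (1.45, SE 0.15) rose, and IGFBP5 and GLI1, a Hedgehog effector, were at least 1.80-fold and 1.52-fold higher. OC90 fell (-2.83, SE 0.21), and CD52, CHI3L1, TIE1 and ADGRF5 were at least 3.84-fold, 2.04-fold, 2.05-fold and 1.80-fold lower. With siRNA #2, MYOF, a membrane-repair ferlin (2.12, SE 0.40), IFI44 (1.63, SE 0.28) and MAMLD1 (1.57, SE 0.16) rose, while DIRC3 and the DNA sensor AIM2 were at least 2.18-fold and 1.68-fold higher. OC90 (-2.58, SE 0.21), STRA6 (-2.51, SE 0.37) and TYRP1 fell, and CHI3L1 and TIE1 were at least 1.81-fold and 1.82-fold lower. With siRNA #3, CES5A, a carboxylesterase, RHD, a blood-group antigen, and ANKRD19P were at least 4.11-fold, 2.09-fold and 2.49-fold higher, and CHGA (2.50, SE 0.18) and CEND1 (2.49, SE 0.30) rose. TYRP1, MYH7B (-3.12, SE 0.31), and CYP19A1, the aromatase (-2.68, SE 0.19), fell, OC90 was 7.98-fold lower, and CHI3L1 was at least 1.82-fold lower. Against each control taken alone, tested after the data were seen, 1, 3 and 8 of the 10 genes named for siRNAs #1, #2 and #3 passed: BFSP1 with siRNA #1, AIM2, MAMLD1 and TYRP1 with siRNA #2, and all but OC90 and CHI3L1 with siRNA #3. With siRNA #1 WIPF3 was 3.50 against NT1 and 0.56 against NT2 (adjusted p = 0.321), and with siRNA #2 OC90 was -5.18 and 0.03 (adjusted p = 0.988). NT1 and siRNA #1 shared no batch, so changes of siRNA #1 against NT1 were reached only through the arrays of siRNAs #2 and #3. The numbers of calls were 894 (437 higher), 628 (341 higher) and 3167 (1418 higher), with medians of all features of -0.07, -0.03 and -0.12. With median centring 82.8%, 69.0% and 76.7% of the calls were higher, against 48.9%, 54.3% and 44.8% here. Without the 4 technical arrays the counts were 123, 295 and 2286. Single samples also moved the counts by over 1.5 times. The siRNA #1 count was 109, 266 and 422 without its samples 34, 24 and 4, 347 and 473 without samples 2 and 22 of NT2, and 563 and 1947 without samples 21 and 11 of NT1. It was 384 and 402 without samples 26 and 6 of siRNA #3, and 449 and 509 without samples 27 and 7 of siRNA #2. The siRNA #2 count was 18 and 46 without its samples 27 and 7, 331 and 354 without samples 2 and 32 of NT2, 1039 without sample 11 of NT1 and 247 without sample 26 of siRNA #3. The siRNA #3 count was 1042 and 1579 without its samples 26 and 6.

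Genes called with all 3 siRNAs in the same direction numbered 138, of which 73 rose and 65 fell. Independent lists would share 0.589, and simulated unchanged groups with the same controls shared 0. Both values leave out the difference between NT1 and NT2, which enters all 3 lists through the shared controls. Neither is therefore the count expected without an effect of the TYRP1 siRNAs. Of the 138, the share that rose was 52.9%, against 76.4% of 140 with median centring and 17.4% of the 23 that also changed at least 2-fold. BFSP1, COL19A1, CHGA, WWC3, ISG15 and ABCB5 were among those that rose, and TYRP1, OC90, CHI3L1, TIE1, FN1, EPHA2 and MAFF among those that fell. For the mean of the 3 siRNAs against NT2 alone, WWC3, OC90, CHI3L1, TIE1, EPHA2 and MAFF did not pass (adjusted p = 0.0545, 0.774, 0.599, 0.29, 0.197 and 0.0597), nor did FN1, which had the other sign (adjusted p = 0.331). The log2 fold changes correlated across genes at r = 0.587 for siRNAs #1 and #2, 0.542 for #1 and #3 and 0.450 for #2 and #3, against 0.294, 0.297 and 0.334 in simulated unchanged groups with the same controls, in which NT1 and NT2 did not differ; genes are not independent replicates. The covariances were 0.0610, 0.0683 and 0.0490, against simulated values of 0.0172, 0.0156 and 0.0176. With the controls split, siRNA #1 against NT2 and the others against NT1, r was 0.101, 0.0571 and 0.730, against simulated values of -0.00148, 0.000546 and 0.525, the last pair still with a shared control, and 25 genes were called in all 3. In that split siRNAs #1 and #2 shared 44 calls of the same sign and 51 of opposite sign, siRNAs #1 and #3 shared 68 and 85, and siRNAs #2 and #3 shared 1587 and 38. Most single samples changed the count by over 1.5 times: it was 10 and 17 without samples 27 and 7 of siRNA #2, 40, 69 and 78 without samples 34, 24 and 4 of siRNA #1, 50 and 66 without samples 26 and 6 of siRNA #3, 66 and 88 without samples 2 and 32 of NT2, and 316 without sample 11 of NT1.

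The TYRP1 siRNAs differed from each other in 1356 features by the moderated F test. The pair of siRNAs #2 and #3 differed most, in 1414 features, against 804 for #1 and #3 and 76 for #1 and #2. With siRNA #3, JPH4, a junctophilin (3.20, SE 0.14, adjusted p = 1e-07), and BMERB1 (3.03, SE 0.40) were higher than with siRNA #2, and CES5A and ANKRD19P were at least 5.33-fold and 3.10-fold higher. MYOF (-3.31, SE 0.44), the growth factor receptor gene FGFR3 (-2.82, SE 0.20) and FA2H, a fatty acid hydroxylase (-2.38, SE 0.31), were lower, and DIRC3 was at least 2.77-fold lower. The lysosome and autophagy list was lower with siRNA #3 than with siRNA #2 (median -0.34; 1 rose and 6 fell of 28; camera adjusted p = 5.25e-06, and adjusted p = 0.0337 with an estimated correlation). Fibroblast markers were lower with siRNA #2 than with siRNA #1 (median -0.21; 1 of 7 fell; camera adjusted p = 0.000316, and adjusted p = 0.0448 with an estimated correlation). The interferon list was higher with siRNA #3 than with siRNA #1 (median 0.46; 9 rose and 0 fell; camera adjusted p = 3.85e-13), a call not held with an estimated correlation (adjusted p = 0.294). The F-test count fell to 405 and 577 without samples 26 and 6 of siRNA #3 and to 445 and 655 without samples 27 and 7 of siRNA #2.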

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

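Of the tests in this part, those on single samples, on siRNA #2 in proportion, on samples that did not choose the calls, on each control and on the interferon genes' relation to TYRP1, and all counts of other splits, were chosen after their results had been seen; the test of proportion to TYRP1 was also divided by siRNA, and the verdict rules of the last interferon test, of leftover batch, of the control siRNAs and of proportion were changed, after the values were seen. A difference among the 3 TYRP1 siRNAs by the F test marked 1356 features and 38 of the 103 named genes. The adjusted p was 4.37e-07 for JPH4, 4.81e-07 for CES5A, 8.36e-06 for TYRP1, 1.88e-05 for FGFR3, 2.57e-05 for RHD, 2.91e-05 for MAMLD1, 7.22e-05 for CCN1 and CYP19A1, 0.000168 for LAMC1 and 0.000301 for WIPF3. It was 0.00124 for CHGA, 0.00134 for FA2H, 0.00138 for CEND1, 0.00144 for BMERB1, 0.00188 for MYOF, 0.00202 for CTSA, 0.00277 for ANKRD19P, 0.00289 for DPP4, 0.00402 for EPHA2, 0.00491 for NDRG1, 0.00699 for CLDN20, 0.00719 for DCN, 0.00799 for ADM and 0.00951 for MYH7B. For HMGA2 and RPS3 it was 0.0106, for COL19A1 0.0157, AIM2 0.0159, ISG15 0.0256, TFRC 0.0261, DIRC3 0.0283, MMP2 0.0307, IGFBP5 0.0337, NPC1 and PLK2 0.0422, SLC45A2 0.0451, CALR 0.0458 and MCAM 0.0462. CCN1 was -0.45 with siRNA #1 and 0.41 with siRNA #2, neither past the threshold, and -1.12 with siRNA #3.

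The first pattern weighed was that NT2 differed from NT1 in 2904 features, against 2554 for the TYRP1 siRNAs, and in 212 without the technical arrays. A single sample does not account for it, since the lowest count with 1 RNA sample left out was 1176. In a fit without sample 6 of siRNA #3, 39.3% of the 1986 calls had the sign of that sample's batch 2 minus batch 1 difference, a share that a batch term removing too much would also leave. An additive batch effect, removed too little or too much, is argued against as the whole cause: in RNA samples that did not choose the calls, siRNAs #2 and #3 differed from NT1 within batch 1, where such an effect cancels, by a median of 0.254 to 0.992 in the direction of NT2, at the lowest 0.352 of the call size. With all samples that median was 0.545, against 0.701 for NT2 minus NT1, and -0.0914 against NT2 within batch 2; an effect of the control siRNAs on the cells is a candidate explanation, but NT1 was in batch 1 alone, so a batch effect on NT1 only and off-target effects stay open.

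The second pattern was the larger number of calls with siRNA #3. With the standard errors of siRNA #1 in place of its own it had 2152 calls instead of 3167, against 894 for siRNA #1, so smaller errors account for part of it and not for all. Proportion was taken between log2 fold changes, and proportion to the share of TYRP1 mRNA lost was not tested. If the genes followed TYRP1 in this way, the other siRNAs would show 0.540 (#1) and 0.723 (#2) of the siRNA #3 change. Over the siRNA #3 calls the median ratio was 0.46 for siRNA #1 and 0.314 for siRNA #2. Measured on siRNA #3 samples that did not choose the calls it was 0.408 to 0.611 and 0.27 to 0.37, the last just over the bound first set against proportion. With 1 sample of siRNA #2 left out as well its ratio was 0.245 to 0.394, below 0.723 by more than this spread although the shared controls raise it, so proportion to TYRP1 is argued against as the whole cause for siRNA #2. For siRNA #1 the same test gave 0.379 to 0.583, so proportion between log2 fold changes stays open there. Off-target effects were not tested, since the labels do not give the siRNA sequences.

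The third pattern was the rise of interferon-response genes. It was not carried by 1 control, since the smaller of the medians against NT1 and NT2 was 0.249 and the larger 0.498. With siRNA #1 the median was 0.117, where 0.247 would follow from the siRNA #3 median in proportion to the TYRP1 log2 fold changes. The difference between siRNAs #1 and #3 did not pass with an estimated correlation (adjusted p = 0.294), so a relation to TYRP1 cannot be told apart from a response to the siRNAs as such.

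Other splits of the RNA samples, in a model of the 2 arms compared, the other siRNAs as groups of their own, and batch, tested whether chance can be excluded. For the pooled comparison 1 of 100 splits, drawn from 3003, gave a count as large, the real one (416, highest other 218). The 416 comes from this model of 2 arms, not from the fit that gave 2554. A chance mix of samples can thus be excluded. The highest others, 218 and 159, kept all NT1 samples in 1 arm, as the real split does, though some that did so gave 0. For siRNA #1 against the controls, 3 of 84 splits gave as many as the real 127, and for siRNA #3, 2 of 84 as many as the real 3098. For siRNA #1 the other splits as large set the 3 samples of NT1 apart (3947) or those of NT2 (307). For siRNA #3 setting NT1 apart gave 6066, and setting NT2 apart 149. Splits that mixed the groups gave at most 3 and 5, so a chance mix of samples can be excluded in both. Any intact group stood apart, the controls included, which points to a structure of the samples, the difference between the controls. These splits therefore cannot tell an effect of siRNA #1, of siRNA #3 or of the pooled TYRP1 siRNAs from other differences between the groups. NT2 against NT1 has 10 splits, too few for a share under 0.05; the real split called 2898 and the highest other 2. For the number of lists, 64 of 100 splits gave at least the real 5, with a highest other of 10, so chance cannot be excluded for the list count.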

How the results depend on the processing

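Of 35 alternatives, 2, batch 3 left out and calls against each control, were chosen after seeing the data. In the 33 that gave a TYRP1 value it lay between -2.88 and -2.34 and passed in 32, all but within batch 2 (-2.39, 2 residual degrees of freedom). Of 290 values of the comparisons 173 were within 1.5 times of the reported count or kept their call; for the others, the cause was not tested except where an alternative has fewer samples or a stricter threshold by construction. In the order pooled, siRNA #1, siRNA #2, siRNA #3, NT2 against NT1, all 3 siRNAs, F test, a change of at least 2-fold as well left 125, 128, 92, 389, 671, 23 and 362. Normexp with quantile normalization gave 1462 for siRNA #1, 988 for siRNA #2 and 227 for all 3. Median centring gave 886 for the F test and 7 lists, and no probe filter 8 lists. The authors' deposited table with batch gave 3916 pooled, 2017, 1277, 358 for all 3 and 2042 for the F test, and without batch 4381, 1630, 1907, 5212, 1182, 425 and 2939. No batch term gave 1080 pooled, 357 for siRNA #1, 6160 for the controls and 65 for all 3. Arrays taken as independent gave 3866 pooled, 1575 for siRNA #2, 5652 for siRNA #3, 1732, 233 and 2869. Without technical arrays siRNA #1 had 123, siRNA #2 295, the controls 212, all 3 siRNAs 39 and the F test 464. Averaged duplicates gave 2109, 372 and 6890 for siRNA #1, siRNA #2 and the controls. Array weights gave 1437, 1030, 5130, 1744, 247 and 3592 from siRNA #1 on, and a trended, robust prior 1365 for siRNA #1. With NT2 as the only control the counts were 606, 501 (siRNA #1), 1393 (siRNA #3) and 79 (all 3); with NT1 they were 5382, 2494, 1437, 5767, 762 (all 3), 869 (F test) and 7 lists. Within batch 2 limma called 0 (3251 at an unadjusted p under 0.05). Leaving out batch 3 gave 837, 73, 154, 1600, 1293, 18 and 455, and calls against each control 140. Leaving out 1 RNA sample gave 1182 to 3781 pooled, 109 to 1947 for siRNA #1, 18 to 1039 for siRNA #2, 1042 to 3849 for siRNA #3, 1176 to 4050 for the controls, 10 to 316 for all 3, 405 to 1655 for the F test and 3 to 6 lists; with 1 siRNA #2 sample left, that sample is assumed to vary like the other groups. A block by the first digit of the sample number written with 2 digits gave 4586 pooled, 1474 for siRNA #2, 1591 for the controls and 237 for all 3. The labels do not say that the digit marks a shared experiment, and not every pair correlated over 0.1 (14 of 22). As a hint from the data, same-digit pairs had a median r of 0.156 against -0.0412 for the others, and 9 of 14 samples correlated best with one of their own digit. Slide equalled batch, so that alternative was not run. Of 4188 values for named genes and list medians 3607 kept their side, 552 lost the threshold, 14 gained it and 15 reversed; 70 of 82 lost it within batch 2, 69 of 124 with NT2 as the only control, 48 of 132 without batch 3 and at most 32 of 132 without 1 RNA sample. With NT2 as the only control, KRCC1 (-0.21), WIPI1 (-0.22) and MOV10 (-0.073) turned negative and OC90 with siRNA #2 (0.022), PLK2 (0.12), FN1 (0.26) and DCN (0.44) positive. Within batch 2 SEL1L (-0.037), WIPI1 (-0.18), TIMP1 (-0.074) and MOV10 (-0.063) turned negative and PLK2 (0.12), FN1 (0.24), DCN (0.22) and TFRC (0.065) positive. Signal over background limits genes dim in a whole group to bounds.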

Other observations

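NT1 samples were further apart than the others. The SD over the brighter features of the difference between 2 RNA samples had a median of 0.474 for NT1. It was 0.226, 0.230, 0.222 and 0.201 for NT2 and siRNAs #1, #2 and #3. Repeated arrays of an RNA sample were averaged first, which can lower the values of siRNAs #2 and #3. NT1, NT2 and siRNA #1 had no repeated arrays. Technical repeats of 1 RNA sample differed by an SD of 0.111 to 0.175 over the same features. The main fit took 1 spread per gene for all groups, so its p-values do not allow for the wider spread of NT1.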
